A study of Mus musculus with 12 samples.

How the data were processed

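The series measured messenger RNA in cultured mesenchymal cells of the mouse small intestine, the connective-tissue cells that lie under the gut epithelium. Per the labels, the cells were primary cells grown to passage 3 and sorted on GFP, with the genotype ColVIcre-MyD88F/F-RosamTmG for the MyD88 knockout (MyD88ko). Cells were serum starved overnight, and the LPS groups then received 2 µg/ml of LPS, a cell-wall component of Gram-negative bacteria, for 6 hours. There were 12 samples in 4 groups of 3: wild type (wt) untreated, wt with LPS, MyD88ko untreated and MyD88ko with LPS. The labels number the replicates and do not say whether they came from separate animals, so the tests measure the spread between libraries as given. The wt samples carry a genotype label without Cre, whereas the design text describes them as Cre-positive, and the conflict could not be settled from the values. If the label is right, MyD88 deletion and Cre cannot be told apart in the comparisons of genotypes. Libraries were 3′ mRNA libraries (QuantSeq) read on an Ion Proton, in which each read comes from the end of a transcript.

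The submitters' processing notes name TopHat2, Bowtie2, DESeq and the mouse genome build mm10, without versions or roles. The authors deposited a table for each of 4 comparisons, with a value for each of the 6 samples compared. Their expression values are scores: normalized read counts per gene, normalized by the authors over all 12 samples and rounded to whole numbers. Of 166719 values given in a pair of tables, 0 differed. The same tables hold the authors' p-value and adjusted p per gene, and the deposited fold change is a ratio of group means after adding 1. A deposited log2 column is the log2 of that ratio, and a deposited fraction per gene is its GC content. The authors' adjustment ran over 15390 genes. The tables list 14907 genes in any comparison and 13951 with values in all 12 samples. They hold 0 mitochondrial genes and 11 symbols with more than a single gene identifier. Of the identifiers, 14874 were found in GENCODE M21, 12598 of them at the same coordinates.

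Totals of the normalized values ranged from 3599944 to 4320551 per sample. Since normalized totals are not depths, the size factor of each library was estimated from the gaps that rounding leaves among low values. The estimates ran from 0.6341 to 1.2916, which gives about 2.5 to 5.3 megareads counted per library; on simulated data the largest error of a size factor was 0.0007. These numbers are up to a common factor and carry no molecule count, since no molecular identifiers were described. Replicates differed by far more than counting error (chi-square per degree of freedom 10.48 to 46.28, pooled over genes); what depth adds to the error of genes with low values was not tested.

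Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3. The test was limma-trend with robust empirical Bayes, in a single fit of all 12 samples with a coefficient per group and 8 residual degrees of freedom. Tested genes had values in all 12 samples and a mean of at least 10 in at least 1 group, which left 12385 genes; 129 genes with such a mean lacked values in part of the samples and were not tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes tested in that comparison. There were 5 comparisons: LPS against untreated in wt and in MyD88ko, MyD88ko against wt untreated and with LPS, and the difference between both LPS responses. All fold changes are on the log2(value + 1) scale, so folds of genes with low values are drawn toward 1. A gene at 0 in all samples of a group is given as listed at 0, without a fold.

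Before the data were examined, 27 gene lists were fixed, among them 6 lists of markers of other cell types, and so were the test, the filters, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members changed were counted after adjustment over all genes and adjusted over the list alone. Named genes were, per comparison: the 10 protein-coding genes highest and the 10 lowest in fold among calls with a mean of at least 20 in the higher group and no overlap between groups, leaving out predicted gene names and duplicated symbols; up to 4 members with the smallest p of each list described; and Myd88, Tlr4, Cd14, Ticam1, Il6, Cxcl1, Ccl2, Ptgs2, Cxcl10 and Grem1. Genes outside this rule are named as chosen after their values were seen, and 3 further lists (abundant epithelial genes, luminal regulators and hepatocyte genes) were written after values were seen.

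Alternatives were a TMM-like rescaling, quantile normalization, limma without trend, no low-value filter, a mean of at least 50, only the groups compared in the fit, a replicate block, pseudocounts of 0.5 and 5, a fold threshold, and leaving out each replicate. After the data were seen, 4 more were added: a correction for GC content, voom on reconstructed counts, protein-coding genes only, and leaving out wt untreated replicates 1 and 3 together. On simulated data with this design, limma called 41 of 100 genes changed 2-fold and 87 of 100 changed 4-fold in the wt LPS comparison. It also called 2 unchanged genes there. For the difference between responses it called 14 and 71 of 100, with 4 unchanged genes called. The simulated spread depended on a gene's mean alone, and no library was set apart for some genes, so these counts need not hold for the real data. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.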

Results

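The data were normalized 3′ read counts per gene in 12 libraries of cultured, GFP-sorted mesenchymal cells of the mouse small intestine, 3 each of wt untreated, wt with LPS, MyD88ko untreated and MyD88ko with LPS. LPS is sensed by the receptor TLR4, which signals through the adaptors MyD88 and TRIF, and the comparisons ask which part of the response to LPS, and of the untreated state, differed when MyD88 was deleted. Estimated counted reads, in megareads, were 3.70, 3.84 and 3.12 in wt untreated, 4.22, 4.65 and 2.50 in wt with LPS, 4.85, 3.56 and 5.06 in MyD88ko untreated, and 5.30, 4.47 and 4.05 in MyD88ko with LPS. The 10 genes with the highest values took 7.4% to 11.1% of the total. Within groups, the log2 values of replicates correlated across genes at Pearson r = 0.924 to 0.957, where genes are not independent replicates. The first principal component held 28.5% of the variance, the second 18.8% and the third 10.2%. On the second, wt untreated replicate 2 stood at 4, against 44.99 and 36.53 for replicates 1 and 3. On the third, MyD88ko LPS replicate 3 stood at 63.14 and all other libraries between −23.13 and 20.6. All untreated libraries came from a lower series of library codes and all LPS libraries from a higher one, so treatment and library series cannot be told apart in any LPS comparison.

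The targeted gene was low in every MyD88ko library. Myd88 (ENSMUSG00000032508, chromosome 9, 119335934 to 119341411, mm10) had normalized values of 99, 98 and 103 in wt untreated and 171, 204 and 213 in wt with LPS. In MyD88ko it had 14, 8 and 10 untreated, and 24, 22 and 5 with LPS. It was 8.85-fold lower in MyD88ko untreated (log2 fold change −3.15 ± 0.43 SE, n = 3 per group, limma adjusted p = 0.000471) and 13.0-fold lower with LPS (−3.70 ± 0.43, adjusted p = 7.07e-05). Without wt untreated replicates 1 and 3 together, an alternative chosen after the data were seen that leaves 1 wt untreated library, the untreated difference was −3.12 and its adjusted p 0.0634. The labels do not name the deleted part of the gene, and a 3′ read can come from a transcript that lacks an exon, so the remaining level does not measure the share of undeleted cells.

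**Figure D1:**
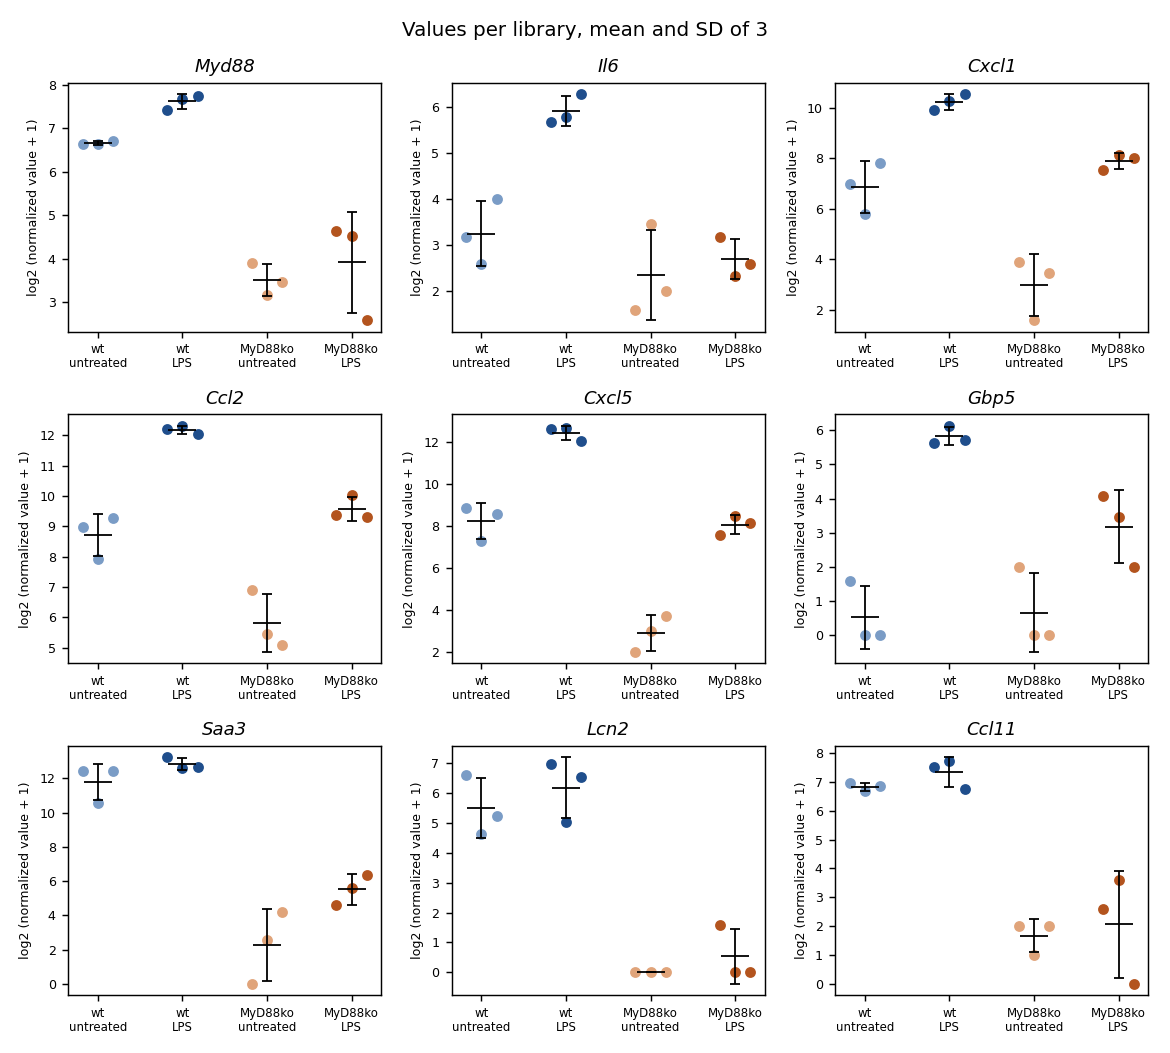
Points are single libraries in the 4 groups, with log2(normalized value + 1) on the vertical axis; the long bar is the mean and the error bar the SD of 3. Myd88 stands below 30 in normalized value in all 6 MyD88ko libraries, and Cxcl5 and Ccl2 are higher with LPS than untreated in both genotypes.

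In wt cells, LPS was followed by higher levels of chemokines and of NF-κB target genes. Cxcl5, a neutrophil chemokine (chromosome 5, 90759360 to 90761624), rose 18.3-fold, from a mean normalized value of 333 ± 160 (SD, n = 3) to 5620 ± 1240 (log2 fold change 4.19 ± 0.43 SE, limma adjusted p = 1.86e-05). Ccl2, a monocyte chemokine, rose 11-fold, from 453 ± 190 to 4660 ± 418 (3.46 ± 0.41, adjusted p = 5.45e-05). Il6, an inflammatory cytokine, rose 6.33-fold, from 9.33 ± 5.13 to 60.3 ± 14.6 (2.66 ± 0.60, adjusted p = 0.00375). Nfkbia, the NF-κB inhibitor that NF-κB itself induces, rose 6.14-fold, from 254 ± 93.2 to 1490 ± 92.3 (2.62 ± 0.24, adjusted p = 1.07e-06).

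Of 15 tested chemokines, 9 rose, 1 fell and 5 were not called, and adjusted over the list alone 9 rose and 1 fell. Besides Cxcl5 and Ccl2, Cxcl1 rose 10.3-fold, Cxcl10, which interferons also induce, 7.98-fold and Ccl7 4.75-fold. The list was higher by camera (adjusted p = 6.12e-06), a call lost with an estimated correlation (adjusted p = 0.136). Of 20 NF-κB genes, 11 rose and 1 fell, and adjusted over the list alone 12 rose and 1 fell. Among them were the adhesion molecule Vcam1 (3.04-fold), the mitochondrial superoxide dismutase Sod2 (2.38-fold) and Tnfaip2 (2.68-fold). This list was higher by camera (adjusted p = 3.45e-06) and with an estimated correlation (adjusted p = 0.00973). Of 35 interferon-stimulated genes, 11 rose and 1 fell, and adjusted over the list alone 16 rose and 1 fell. The guanylate-binding protein Gbp5 rose 39.3-fold and the viral RNA sensor Ddx58 2.18-fold, whereas the immunity-related GTPase Irgm1 fell 3.00-fold. The interferon list was higher by camera (adjusted p = 6.53e-05), with adjusted p = 0.469 with an estimated correlation.

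In wt cells, 8 of 16 contractile genes rose and 1 fell, with the same counts adjusted over the list alone, among them Tagln (2.73-fold) and Actg2 (1.88-fold), which encode proteins of the actin apparatus. The list's camera adjusted p was 0.0405, and 0.419 with an estimated correlation. Of 37 structural matrix genes, 5 rose and 0 fell (4 and 0 adjusted over the list alone), including the collagen crosslinker Lox (1.90-fold) and the fibrillin Fbn1 (2.53-fold). The matrix list's camera adjusted p was 0.0178, and 0.731 with an estimated correlation and 0.228 by fry. The contractile call was lost without wt untreated replicate 1 (adjusted p = 0.115) or 3 (0.0531) and without wt LPS replicate 1 (0.067) or 2 (0.0621). It was also lost with a replicate block (0.0881), after GC correction (0.0542) and without both wt untreated replicates 1 and 3 (0.216). The matrix call was lost without wt untreated replicate 1 (0.115) or 3 (0.298) and without wt LPS replicate 2 (0.318), and without both wt untreated replicates 1 and 3 the list's direction turned (adjusted p = 0.631).

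Among the genes that fell most in wt cells, several were far higher in some untreated libraries than in others. Gata3, a transcription factor of luminal epithelia and T cells, had 957, 23 and 258 in wt untreated replicates 1, 2 and 3 and at most 19 in any other library. It was 49.9-fold lower with LPS (log2 fold change −5.64 ± 0.99 SE, adjusted p = 0.00066), and the call was lost by voom (adjusted p = 0.277) and without both replicates 1 and 3 (0.18). Cldn4, a tight-junction protein of epithelia, had 213, 7 and 122 in the same libraries, and Cdh1, the epithelial cadherin, 3, 0 and 719; Cdh1 was chosen after its values were seen. Serpina3k, a serine protease inhibitor of liver, had 19, 188 and 57 in wt untreated and 35, 59 and 85 in MyD88ko untreated, and was listed at 0 in all 6 LPS libraries. The intestinal mucin Muc2, chosen after its values were seen, was listed at 0 in all 6 untreated libraries and had 16, 32 and 11 in wt with LPS and 4, 0 and 11 in MyD88ko with LPS.

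In all, limma called 2380 of 12385 genes between wt LPS and wt untreated, 1183 higher and 1197 lower, and 3966 at an unadjusted p under 0.05. Pseudogenes made up 12.94% of the calls and 5.82% of the genes tested. The count was 1571 with a fold threshold of 2, 1570 without wt LPS replicate 1 and 969 without wt untreated replicates 1 and 3 together, and of 65 named genes called here 46 stayed called whichever library was left out and 27 stayed called without both of these replicates. Among those lost without both were Lox (adjusted p = 0.0705), Fbn1 (0.289), Actg2 (0.0881) and Irgm1 (0.114).

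**Figure D2:**
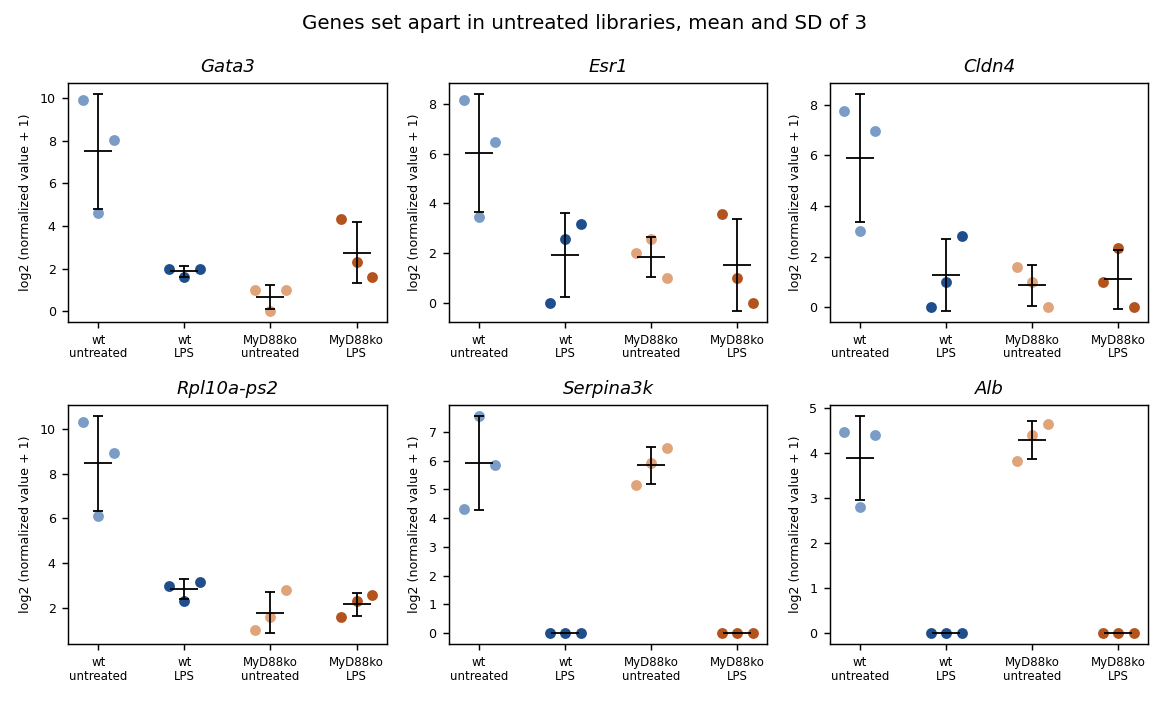
Points are single libraries in the 4 groups, with log2(normalized value + 1) on the vertical axis; the long bar is the mean and the error bar the SD of 3. Rpl10a-ps2, a pseudogene, and Alb were chosen after their values were seen. Gata3, Esr1, Cldn4 and Rpl10a-ps2 stand high in wt untreated replicates 1 and 3, and Serpina3k and Alb are listed at 0 in all 6 LPS libraries.

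In MyD88ko cells, chemokines still rose with LPS, from lower levels. Cxcl5 rose 35.9-fold, from 7.33 ± 4.51 (SD, n = 3) to 275 ± 81.1 (log2 fold change 5.16 ± 0.43 SE, limma adjusted p = 2.3e-05). Cxcl1, another neutrophil chemokine, rose 30.1-fold (4.91 ± 0.55, adjusted p = 0.000288) and Ccl2 13.5-fold, from 64.7 ± 46.5 to 781 ± 230 (3.76 ± 0.41, adjusted p = 0.000166). Il6 was not called: it had 5 ± 4.36 untreated and 5.67 ± 2.08 with LPS (0.34 ± 0.60, adjusted p = 0.794).

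Of the 15 chemokines, 9 rose, 0 fell and 6 were not called, also adjusted over the list alone. Cxcl10 rose 10.2-fold and Ccl7 3.27-fold, and the list was higher by camera (adjusted p = 1.71e-08) and with an estimated correlation (adjusted p = 0.0467). Of the 20 NF-κB genes, 4 rose and 0 fell, and adjusted over the list alone 10 rose and 1 fell. Nfkbia rose 2.20-fold, from 177 ± 22.0 to 389 ± 32.7, and Bcl3, a nuclear partner of NF-κB, rose 6.32-fold, a call lost by voom (adjusted p = 0.0979). The NF-κB list was higher by camera (adjusted p = 0.000285) and with an estimated correlation (adjusted p = 0.0391). Of 35 interferon-stimulated genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0535). Fgf7, a growth factor that mesenchyme makes for epithelium, rose 8.51-fold, a call lost with only the groups compared in the fit (adjusted p = 0.0692). Its untreated values were near the floor, so the size of that fold depends on the pseudocount. Junb, an immediate-early transcription factor, rose 3.71-fold. Serpina1a, another hepatocyte protease inhibitor, fell 6.63-fold, from 64, 64 and 61 to 19, 8 and 4.

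In all, 741 genes were called in MyD88ko cells, 320 higher and 421 lower, and 2600 at an unadjusted p under 0.05; pseudogenes made up 17% of the calls. The count was 435, 337 and 383 without MyD88ko untreated replicate 1, 2 and 3, and 425 by limma without trend. Of the calls, 240 were higher and 292 lower in both genotypes, against 30.6 and 40.7 for independent lists, and 0 were called in opposite directions. Both LPS comparisons took each gene's spread from the same fit, which alone can raise the overlap above that of independent lists. That overlap of 532 was 328 with a fold threshold of 2, 312 by limma without trend, and 316, 285 and 311 without MyD88ko untreated replicate 1, 2 and 3.

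Untreated MyD88ko cells had far lower levels of acute-phase and antimicrobial genes and of chemokines than untreated wt cells. Saa3, an acute-phase apolipoprotein (chromosome 7, 46711998 to 46715700), was 751-fold lower, at 7.33 ± 8.74 against 4160 ± 2280 (SD, n = 3; log2 fold change −9.55 ± 0.95 SE, limma adjusted p = 0.000963). Cp, the copper-carrying ferroxidase ceruloplasmin, was 38.9-fold lower (−5.28 ± 0.58, adjusted p = 6.14e-05), and Cxcl5 40.5-fold lower (−5.34 ± 0.43, adjusted p = 1.25e-05). Lcn2, an antimicrobial protein that binds bacterial siderophores, was listed at 0 in all 3 MyD88ko libraries and had a mean of 52.7 in wt, and its call was lost without both wt untreated replicates 1 and 3 (adjusted p = 0.0922).

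Of 15 acute-phase, complement and antimicrobial genes, 10 fell and 0 rose, and 15 fell adjusted over the list alone; C1ra, a protease of the complement cascade, fell 3.01-fold. The list was lower by camera (adjusted p = 3.32e-19) and with an estimated correlation (adjusted p = 0.000344). Of 15 chemokines, 7 fell and 0 rose (8 and 0 adjusted over the list alone), among them the eosinophil chemokine Ccl11 (36.0-fold), Ccl2 (7.52-fold) and Ccl7 (4.63-fold); without both wt untreated replicates 1 and 3 the Ccl2 call was lost (adjusted p = 0.142). The chemokine list was lower by camera (adjusted p = 4.3e-12) and with an estimated correlation (adjusted p = 0.0178). Of 20 NF-κB genes, 2 fell and 0 rose (4 and 0 adjusted over the list alone): Nfkbiz 5.16-fold and Bcl3 11.7-fold, with camera adjusted p = 0.00326 and adjusted p = 0.0396 with an estimated correlation. The Bcl3 call was lost by voom (adjusted p = 0.0771) and without both replicates 1 and 3 (0.33).

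Of 25 Wnt, BMP and growth factor genes of the stem cell niche, 5 fell and 2 rose (8 and 2 adjusted over the list alone). Fgf7 fell 34.3-fold, from 43 ± 10 to 0.333 ± 0.577, and the Wnt antagonist Sfrp1 fell 4.84-fold; the list's camera adjusted p was 0.0246, and 0.0973 with an estimated correlation, and the call was lost without wt untreated replicate 2 (0.109) or MyD88ko untreated replicate 2 (0.0515). Pdgfra, a receptor that marks fibroblasts, fell 3.58-fold, and Mmp9, a gelatinase, 7.69-fold. Of 16 contractile genes, 2 rose and 0 fell (9 and 0 adjusted over the list alone), and the list was higher by camera (adjusted p = 2.22e-06) and with an estimated correlation (adjusted p = 0.0185). Chodl, a membrane lectin, was 10.5-fold higher in MyD88ko, at 110 ± 59.8 against 9 ± 3.46, and lost its call without both wt untreated replicates 1 and 3 (adjusted p = 0.0566). Gata3, highest in wt untreated replicates 1 and 3, was 114-fold lower in MyD88ko (limma adjusted p = 0.000963). Its call was lost with only the groups compared in the fit (adjusted p = 0.0506), by voom (0.47) and without both of these replicates (0.298).

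In all, 233 genes were called between the untreated genotypes, 98 higher and 135 lower in MyD88ko, and 1923 at an unadjusted p under 0.05; pseudogenes made up 14.16%. The count was 83, 412 and 150 without wt untreated replicate 1, 2 and 3, 88 and 64 without MyD88ko untreated replicate 2 and 3, 74 by limma without trend, 125 by voom, and 37 without both wt untreated replicates 1 and 3. Of 42 named genes called here, 23 stayed called whichever library was left out and 12 stayed called without both of these replicates.

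With LPS, MyD88ko cells were below wt cells in NF-κB genes, chemokines and acute-phase genes. Il6 was 9.32-fold lower, at 5.67 ± 2.08 against 60.3 ± 14.6 (SD, n = 3; log2 fold change −3.22 ± 0.60 SE, limma adjusted p = 0.00539). Nfkbia was 3.82-fold lower (−1.94 ± 0.24, adjusted p = 0.000121), Ccl7 6.73-fold lower (−2.75 ± 0.26, adjusted p = 8.84e-06) and Cp 43.7-fold lower (−5.45 ± 0.58, adjusted p = 2.81e-05). Cxcl1 was not called (−2.32, adjusted p = 0.0617).

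Of 20 NF-κB genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone), among them Nfkbiz (7.86-fold), Sod2 (3.06-fold) and Bcl3 (9.71-fold). The list was lower by camera (adjusted p = 1.23e-09) and with an estimated correlation (adjusted p = 0.00127). Of 15 chemokines, 5 fell and 0 rose (8 and 0 adjusted over the list alone), among them Cxcl5 (20.6-fold) and the membrane-bound chemokine Cxcl16 (5.61-fold). The chemokine list was lower by camera (adjusted p = 3.06e-13) and with an estimated correlation (adjusted p = 0.00891). Of 15 acute-phase genes, 8 fell and 0 rose (14 and 0 adjusted over the list alone), among them Saa3 (157-fold), Lcn2 (50.6-fold) and the long pentraxin Ptx3 (4.47-fold). This list was lower by camera (adjusted p = 2.08e-21) and with an estimated correlation (adjusted p = 0.000228). Of 35 interferon-stimulated genes, 2 fell and 0 rose (5 and 0 adjusted over the list alone), with camera adjusted p = 3.06e-07 and adjusted p = 0.14 with an estimated correlation.

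Of 9 prostaglandin genes, 2 fell and 0 rose (4 and 0 adjusted over the list alone); Ptges, the inducible prostaglandin E synthase, fell 4.90-fold, and Ptgs2 (COX-2) was not called, at 232 against 644 (adjusted p = 0.303). The list was lower by camera (adjusted p = 0.00126) and with an estimated correlation (adjusted p = 0.0301). Of 24 matrix proteases and inhibitors, 4 fell and 0 rose (8 and 2 adjusted over the list alone), with Mmp9 6.82-fold and the plasminogen activator Plat 2.65-fold lower, the latter not called with a replicate block (adjusted p = 0.0893); camera gave adjusted p = 0.00537 and an estimated correlation adjusted p = 0.0471. Of 25 niche genes, 5 fell and 2 rose (10 and 3 adjusted over the list alone), with Fgf7 12.6-fold and Igf1 2.53-fold lower and Wnt5a 2.18-fold higher. The Igf1 call was lost by limma without trend (adjusted p = 0.0605) and with a replicate block (0.0646), and the Wnt5a call with the block (0.0762). The niche list was lower by camera (adjusted p = 0.00266) and with an estimated correlation (adjusted p = 0.0471). Gna14, a G protein subunit, was 14.7-fold higher in MyD88ko, and Chodl 10.6-fold.

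In all, 185 genes were called between the genotypes with LPS, 56 higher and 129 lower in MyD88ko, and 1486 at an unadjusted p under 0.05; pseudogenes made up 1.08%. The count was 85 and 122 without wt LPS replicate 1 and 2, 113 without MyD88ko LPS replicate 2, 112 by limma without trend and 85 with a replicate block. This comparison and the untreated one share no libraries, but both took each gene's spread from the same fit. In both, 18 genes were higher and 47 lower in MyD88ko, and 0 were called in opposite directions. Independent lists would give 0.443 and 1.41, but the shared spread alone can raise the overlap.

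**Figure D3:**
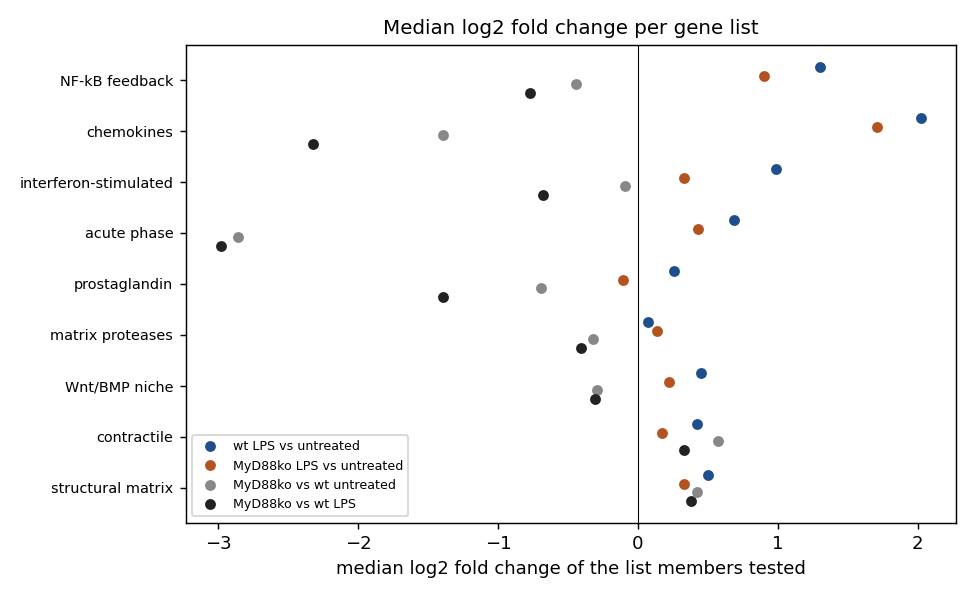
Each point is the median log2 fold change of the tested members of a gene list (horizontal axis), with the lists on the vertical axis and a colour for each of 4 comparisons. Chemokines have medians of 2.02 in wt and 1.71 in MyD88ko with LPS against untreated, and acute-phase genes −2.86 and −2.98 in MyD88ko against wt, untreated and with LPS.

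The last comparison tested whether the LPS response, as a log2 fold change, differed between genotypes. Ackr4, a scavenging receptor for chemokines, had 1030 ± 378 (SD, n = 3) untreated and 155 ± 39.6 with LPS in wt, and 893 ± 134 and 681 ± 189 in MyD88ko; the responses differed by a log2 value of 2.27 ± 0.38 SE (limma adjusted p = 0.0468). Selenom, a selenoprotein of the endoplasmic reticulum, had 294 ± 12.9 and 1410 ± 167 in wt and 763 ± 84.0 and 1090 ± 262 in MyD88ko (−1.76 ± 0.28, adjusted p = 0.0468). The NF-κB list responded less in MyD88ko, with a median difference of −0.45 (camera adjusted p = 0.0285, and 0.244 with an estimated correlation and 0.126 by fry), and so did the interferon-stimulated list, with −0.29 (adjusted p = 0.0285, and 0.871 with an estimated correlation and 0.698 by fry); 0 members of either were called, and adjusted over the list alone 3 and 0 fell. The difference was not called for chemokines (median 0.12, camera adjusted p = 0.832) or acute-phase genes (−0.10, adjusted p = 0.964). In summed normalized values, however, the 15 chemokines rose by 10500 in wt and by 1100 in MyD88ko. For Il6, called in wt alone, the difference was −2.32 (95% interval −4.08 to −0.56, adjusted p = 0.394), so the response was not shown to differ after adjustment.

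Limma called 2 of 12385 genes in this comparison and 1137 at an unadjusted p under 0.05. The count was 0 without wt LPS replicate 1 or 2, any single MyD88ko untreated replicate, or MyD88ko LPS replicate 1 or 3, 1 without wt untreated replicate 1, 44 without wt untreated replicate 2 and 16 without replicate 3. It was also 0 by limma without trend (adjusted p = 0.275 for both genes), with a mean of at least 50 (0.0503) and with a pseudocount of 0.5 (0.0525), 1 after GC correction, 4 with quantile normalization, 4 with a replicate block and 14 without both wt untreated replicates 1 and 3. Ackr4 lost its call without wt LPS replicate 1 (adjusted p = 0.291) or 2 (0.145), MyD88ko untreated replicate 1 (0.158), 2 (0.115) or 3 (0.163), and MyD88ko LPS replicate 1 (0.0571), 2 (0.111) or 3 (0.0978). Selenom lost its call without wt untreated replicate 1 (0.114), wt LPS replicate 1 (0.291), 2 (0.125) or 3 (0.0979), MyD88ko untreated replicate 1 (0.142), 2 (0.115) or 3 (0.163), and MyD88ko LPS replicate 1 (0.0856) or 3 (0.0978), and also after GC correction (0.196) and without both wt untreated replicates 1 and 3 (0.0678). Without 1 library the NF-κB call was lost for wt untreated 2 (adjusted p = 0.0797), wt LPS 2 (0.392), MyD88ko untreated 1 (0.112) and MyD88ko LPS 1 (0.158), and the interferon call for wt untreated 2 (0.105), wt LPS 2 (0.392), MyD88ko untreated 1 (0.112), MyD88ko LPS 2 (0.275) and MyD88ko LPS 3 (0.147).

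The authors' own adjusted p, from their tables, was under 0.05 for 631 genes between wt LPS and untreated (250 higher and 381 lower), 106 in MyD88ko (58 and 48), 230 between the untreated genotypes (20 higher and 210 lower in MyD88ko) and 77 with LPS (13 and 64). Of those tested here, 536 of 565, 87 of 106, 112 of 171 and 64 of 77 were called in the same direction.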

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

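The limma, camera, estimated correlation and fry tests were planned, whereas the draws and splits of the sample labels and the tests that weigh explanations were chosen after the result was seen. The difference between the LPS responses singled out 2 genes and 2 lists, because the genotypes differed there in a test of the difference itself. The response of Selenom was smaller in MyD88ko by limma (log2 difference −1.76), and that of Ackr4 differed by 2.27. The lists of NF-κB genes and of interferon-stimulated genes rose less in MyD88ko, each with a camera adjusted p of 0.0285, and both calls were lost with an estimated correlation (0.244 and 0.871) and by fry (0.126 and 0.698). Of 100 draws of the sample labels, the real labelling included, 8 gave at least the 2 genes of the real one, itself among them. The draws exchanged genotype labels within a treatment, which carries the difference between the genotypes into this comparison. They therefore cannot decide whether chance gives that count, and chance is not excluded. The highest other draw gave 471 genes. It exchanged the untreated labels of the genotypes, so it tested the sum of the genotype differences untreated and with LPS.

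For the other comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real counts were 2380, 741, 233 and 185 genes, and the highest other splits gave 0, 1, 0 and 0; in each comparison 1 split, the real one, reached its count.

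The first pattern is the 46 genes that were lower in both wt LPS and MyD88ko untreated libraries than in wt untreated libraries, such as Gata3. Pseudogenes made up 39.1% of them against 5.82% of all genes tested (Fisher p = 2.89e-11), which reads from another organism could give. Epithelial cells in the sorted culture may be a source, but abundant epithelial genes over luminal regulators had a ratio of medians of 0.112 in replicate 1 and 0.932 in replicate 3, which does not decide it; narrower first lists gave 0.0317 and 1.1, and of the 16 epithelial genes 6 were measured in all samples, 1 was expressed in all groups and 8 are in other lists. For its 18 pseudogenes, the 90th percentile of replicate 2 over the mean of replicates 1 and 3 was 0.144, but this rests on a single library, and an effect of the wt untreated state of unequal size stays open. For its 26 protein-coding genes that percentile was 1.13, and such an effect stays open there too.

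The second pattern is the LPS response that stayed in MyD88ko. Undeleted cells that express Myd88 and respond as wt cells do could carry it, in which case the rise of a list in MyD88ko over that in wt would be at most the share of Myd88 left, 0.107 untreated and 0.0867 with LPS; reads of deleted transcripts only add to that share, so it bounds undeleted cells from above. The ratio was 0.272 for NF-κB genes (0.241 to 0.291 without any 1 library), 0.105 for chemokines and 0.623 for interferon-stimulated genes (0.0719 without MyD88ko LPS replicate 1). Minus the share of Myd88, its 95% interval had a lower end of 0.0465 or more for NF-κB genes. Without Vcam1 that lower end was −0.0017. Since the result rests on 1 gene, such cells are not excluded as the whole source of that list's summed rise. For chemokines and interferon-stimulated genes the lower ends were −0.14 and −1.11, and undeleted cells stay open there too.

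The third pattern is that the 532 LPS calls shared by both genotypes were rich in pseudogenes. After each library's GC trend was removed, 537 shared calls were left, 478 of the 532 among them. Such a trend therefore did not account for most of the shared calls. Their share of pseudogenes was not computed again, so GC content stays open as a cause of that share. Pseudogenes made up 19.9% of the shared calls (Fisher p = 1.58e-30), which the library series could give, but LPS and series are the same split here. Hepatocyte RNA in the untreated libraries is a candidate, although the cells were sorted on GFP. Of 19 measured hepatocyte genes, 17 had a higher mean in untreated libraries in both genotypes, the exceptions being Hp and Mt1. A narrower first list gave 14 of 14. These lists were written after values were seen, so part of such a count can be built in. Of the 532 shared calls, 4 are in the wider list. That count cannot pass the list's 19 measured genes, so it does not weigh against this source. The list's highest member untreated was Mt1 at 575, against 17.3 for Alb. Mt1 also had 374 to 1131 in the LPS libraries, so its place above Alb does not decide the question. Of the 34 genes of the wider list, 4 were expressed in all groups and 3 are in other lists.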

How the results depend on the processing

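For every change given here the cause was not tested. Of the alternatives, 4 were chosen after the data were seen: GC correction, voom on reconstructed counts, protein-coding genes only, and leaving out wt untreated replicates 1 and 3 together. The last leaves 1 wt untreated sample, taken to vary like the other groups.

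For wt LPS, 2380 genes became 1571 with a fold threshold of 2 and 969 without both of these replicates, and 1570 to 1947 without any 1 library. For MyD88ko LPS, 741 became 425 by limma without trend, and 337 to 652 without 1 library. For the untreated genotypes, 233 became 74 without trend, 125 by voom and 37 without both replicates, and 64 to 412 without 1 library. For the genotypes with LPS, 185 became 112 without trend and 85 with a replicate block, and 85 to 189 without 1 library. For the difference between responses, 2 genes became 4 with quantile normalization, 4 with a replicate block, 14 without both replicates, 1 after GC correction, and 0 without trend, with a mean of at least 50 or with a pseudocount of 0.5, and 0 to 44 without 1 library. By limma at an unadjusted p under 0.05 there were 1137 genes in that comparison.

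Whether replicate numbers pair the samples was not settled. Residuals of samples with the same number correlated at 0.06, 0.17 and 0.06 between wt untreated and LPS. Those with different numbers correlated at −0.1 to 0.04. In MyD88ko, the same number gave 0.13, 0.04 and −0.05, and different numbers gave −0.16 to 0.11. With 3 libraries per group these values cannot decide it.

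Myd88 was lower in MyD88ko untreated by −3.12 without both replicates (adjusted p = 0.0634), and by −3.34 to −2.97 without 1 library; with LPS the range was −4.06 to −3.03. The overlap of 532 LPS calls was 328 with the fold threshold and 312 without trend, and 285 to 497 without 1 library.

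Of 5 lists called in wt LPS, 1 was left with an estimated correlation, 3 without both replicates and 9 were called by fry, with 3 to 6 without 1 library. The 2 lists called in MyD88ko LPS became 5 with quantile normalization and 5 with a replicate block, and 3 to 5 without 1 library. Of 16 between untreated genotypes, 4 were left with an estimated correlation and 10 without both replicates, and 10 to 15 without 1 library. Of 17 with LPS, 6 were left with an estimated correlation, and 10 to 17 without 1 library. For the difference, 2 lists became 0 with an estimated correlation, 0 by fry and 4 without both replicates, and 0 to 2 without 1 library.

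The adjusted p for the difference of the NF-κB list was 0.244 with an estimated correlation and 0.126 by fry, and 0.0116 to 0.392 without 1 library. For the interferon list it was 0.871 and 0.698, and 2.31e-05 to 0.392. For chemokines the range without 1 library was 0.406 to 0.961, and for acute-phase genes 0.647 to 0.998.

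Directions of lists reversed in 4 cases, all without both wt untreated replicates 1 and 3: structural matrix genes in wt LPS (adjusted p = 0.631), between the untreated genotypes (0.414) and in the difference (0.0178), and proliferation genes between the untreated genotypes (0.702).

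Among named genes that were called, Myd88 aside in the comparisons of genotypes, 129 of 1224 results under the alternatives lost the call in wt LPS and 111 of 668 in MyD88ko LPS. Between untreated genotypes it was 123 of 766, with LPS 107 of 850, and for the difference 25 of 48, from 2 genes. For called lists, 16 of 70, 0 of 26, 50 of 224, 40 of 221 and 13 of 40 results in the 5 comparisons lost the call or its direction.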

Other observations

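Several metabolic and stress lists had not been described. Between the untreated genotypes, cholesterol synthesis genes were lower in MyD88ko (camera adjusted p = 0.000443, and 0.327 with an estimated correlation), as were proliferation genes (0.00898 and 0.367), oxidative stress genes (0.0246 and 0.232) and glycolysis and hypoxia genes (0.04 and 0.232). Of the 20, 31, 12 and 21 tested members of these lists, 0 were called over all genes. Cytokines (0.00264 and 0.0671), genes of the TLR4 pathway (0.0139 and 0.0671), other innate receptors (0.0209 and 0.0761), prostaglandin genes (0.0139 and 0.0671) and matrix proteases (0.0355 and 0.0923) were also lower. Adjusted over all genes, 1 of 13 cytokines, 1 of 24 TLR4 pathway genes and 0 of 11 other innate receptors fell. So did 2 of 9 prostaglandin genes and 2 of 24 matrix proteases, and 0 members of these lists rose. The median log2 fold change of the TLR4 pathway list was −0.2 and its mean −0.51. Myd88, the deleted gene, was itself called lower here, and its part in that list's call was not tested. Structural matrix genes were higher (0.000293 and 0.384), with 1 of 37 members called as higher and 0 as lower. By fry the calls were lost for structural matrix (0.211), proliferation (0.218), cholesterol (0.178), oxidative stress (0.0889) and glycolysis and hypoxia genes (0.0889). Without wt untreated replicates 1 and 3 together, the direction reversed for structural matrix genes (0.414) and proliferation genes (0.702), and the calls were lost for cholesterol (0.802), oxidative stress (0.948), glycolysis and hypoxia (0.314), cytokine (0.052) and prostaglandin genes (0.0882).

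Single libraries also ended calls between the untreated genotypes. Without wt untreated replicate 1, the call was lost for glycolysis and hypoxia genes (0.105). Without wt untreated replicate 2 it was lost for those (0.0568), other innate receptors (0.0652) and matrix proteases (0.153). Leaving out wt untreated replicate 3 ended it for proliferation (0.156), cholesterol (0.0546), oxidative stress (0.169), glycolysis and hypoxia genes (0.0674) and matrix proteases (0.0658). MyD88ko untreated replicate 1 mattered for matrix proteases (0.056), replicate 2 for the TLR4 pathway (0.0519), proliferation (0.0519) and glycolysis and hypoxia genes (0.0678), and replicate 3 for matrix proteases (0.0662), proliferation (0.053), oxidative stress (0.0794) and glycolysis and hypoxia genes (0.0603).

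With LPS, MyD88ko cells were lower than wt in glycolysis and hypoxia genes (camera adjusted p = 0.00145, and 0.0797 with an estimated correlation), oxidative stress genes (0.00266 and 0.14), cholesterol genes (0.00537 and 0.429), other innate receptors (0.0237 and 0.0836), cytokines (0.0433 and 0.147), antigen presentation genes (0.0438 and 0.147) and mesenchymal identity genes (0.0418 and 0.14). Adjusted over all genes, 1 of 21 glycolysis and hypoxia genes, 1 of 13 cytokines and 3 of 13 mesenchymal identity genes fell, and 0 rose. Of 12 oxidative stress genes, 20 cholesterol genes, 11 other innate receptors and 12 antigen presentation genes, 0 were called. Contractile genes (0.0017 and 0.0605) and structural matrix genes (0.00715 and 0.539) were higher as lists. Of 16 contractile genes 0 were called, and of 37 structural matrix genes 0 rose and 1 fell. Quantile normalization ended the calls of contractile (0.224) and structural matrix genes (0.396) and of cytokines (0.11), and a replicate block those of cytokines (0.221) and antigen presentation genes (0.107). The antigen presentation call was also lost with members of 1 list only (0.153), and by fry those of structural matrix (0.452) and cholesterol genes (0.305). Of these calls, some were lost without wt LPS replicate 1: antigen presentation (0.0687) and structural matrix genes (0.0806). Without wt LPS replicate 2 it was antigen presentation (0.0915) and mesenchymal identity genes (0.0545). Without wt LPS replicate 3 it was cytokines (0.167), other innate receptors (0.0864), antigen presentation (0.0864), cholesterol (0.105), mesenchymal identity (0.0921) and structural matrix genes (0.111). MyD88ko LPS replicate 2 mattered for cytokines (0.0641), antigen presentation (0.161) and structural matrix genes (0.0641), and replicate 3 for those (0.0969, 0.13 and 0.0836), other innate receptors (0.0969), cholesterol (0.119) and mesenchymal identity genes (0.17). Lists of angiogenesis, immediate-early and endoplasmic reticulum stress genes were not called by camera in this comparison (adjusted p = 0.62, 0.212 and 0.994).

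Of the marker lists of other cell types, 5 had 2 tested members each and were not tested as lists. Glia and interstitial cell markers, with 5, were lower in MyD88ko untreated (camera adjusted p = 0.0415, and 0.232 with an estimated correlation) and with LPS (0.0125 and 0.14). The untreated call was lost without wt untreated replicate 2 (0.0568) or 3 (0.116) and MyD88ko untreated replicate 1 (0.056) or 2 (0.111), by fry (0.13), with quantile normalization (0.0583) and without both wt untreated replicates 1 and 3 (0.257), and the LPS call without wt LPS replicate 3 (0.111) or MyD88ko LPS replicate 3 (0.0969). Between LPS and untreated libraries this list was not called (camera adjusted p = 0.265 in wt and 0.386 in MyD88ko), yet 2 of its 5 members rose in wt and 1 in MyD88ko, calls that were not refitted. Its summed values were 783, 650 and 1016 in wt untreated against 2419, 1388 and 3049 with LPS, and 687, 425 and 513 against 1727, 1058 and 1011 in MyD88ko. Summed values of epithelial markers were 190, 6 and 866 in wt untreated and at most 55 in any other library. Macrophage markers summed to at most 78, endothelial to at most 41 and mesothelial to at most 91 in any library, and lymphocyte markers ran from 37 to 416.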
